A study of Mus musculus with 4 samples.

How the data were processed

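Nuclei of mouse hippocampus were profiled with the Chromium 3' v3.1 chemistry, per the labels, in 4 libraries named Trained replicates 1 and 2 and Untrained replicates 1 and 2. The deposited values are UMI counts per gene and barcode, written by Cell Ranger 7.0.0 per the file headers. Per the submitters' processing notes, Cell Ranger 8 and STAR were used with the GRCm39 build, which is at odds with the version in the headers. All 4 libraries share 32285 features, of which 32158 (99.6%) have a gene ID found in GENCODE vM21, and genes were joined by ID. No genome position is used here. Nuclei carrying the eYFP tag and the spatial data from the same study were not analysed here.

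The deposited barcodes reach far below the depth of a nucleus. Trained replicates 1 and 2 and Untrained replicates 1 and 2 held 73013, 65863, 79810 and 41903 barcodes. In the same order, the lowest barcode held 101, 174, 201 and 251 UMIs, and the mode was at 204, 204, 324 and 295 UMIs. Bins next to the lowest barcode were left out of the search for the mode. In Trained replicate 2 the mode is the lowest bin searched, so its true peak may lie lower and amounts taken from it are uncertain. Barcodes up to 1.25 times that mode are called low-UMI barcodes and were summed as a profile of free RNA. They may also hold RNA of nuclei, which was not separated. Nuclei were barcodes with at least 1000 UMIs, at least 500 genes and at most 5% mitochondrial UMIs, which left 791, 4560, 7728 and 7008. Doublets were scored in each library by the share of simulated doublets (2 for each nucleus) among a nucleus's neighbours, a method written here after Scrublet. The automatic threshold marked at most 0.0658% of nuclei, so nuclei above the score that at most 8% exceed were marked instead and removed, a rule set after the data were seen. This marked 6.57%, 7.65%, 7.73% and 7.93% of the nuclei.

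Counts were scaled to 10000 per nucleus and log-transformed, 2000 variable genes and 30 principal components were taken, and a graph of 20 neighbours was clustered with the Leiden method at resolution 1 (seed 1). A cluster of at least 20 nuclei took the name of the best of 22 marker sets when its mean log2 fold over all other nuclei (20 CPM added to both) was at least 0.8, at least 3 markers were above 0.5, and no other class had more markers among its top 10 genes. The marker sets were fixed before the data were examined and these thresholds after. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9.

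Counts were summed per class and library, so that the library and not the nucleus is the unit of replication. A class was tested when every library held at least 30 of its nuclei. In R 4.3.3, edgeR 4.0.16 was used with filterByExpr, TMM scaling and the quasi-likelihood F test of trained against untrained, and p was adjusted by the Benjamini-Hochberg method within each class at 0.05. The standard error of a log2 change is its absolute value divided by the square root of F. Shares of nuclei were tested with the same edgeR fit on nuclei per class and with an exact permutation of libraries (6 splits). For the interaction, the effect of training was compared between classes with the library as a block. Gene lists, 30 in number and fixed before the data were examined, held 689 genes, of which 687 were found; a list was tested with at least 5 tested members by camera in limma 3.58.1 with a correlation of 0.01. The list of reactive astrocyte genes had fewer than 5 tested members in every class.

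The rule for naming genes was also fixed before the data were examined. In dentate granule, CA1 and CA3 nuclei the text names up to 12 called genes in each direction, and in other classes up to 4, if both trained libraries lie on the same side of both untrained ones. Where fewer than 4 pass, those with the smallest unadjusted p fill up to 4. Mitochondrial, ribosomal protein, predicted and sex genes are left out of this ranking. A further 11 genes of memory and plasticity are named wherever they passed the count filter; Fos did so in no class and Npas4 in CA1 nuclei alone. For each gene list described, the text names 2 to 4 members with the smallest p.

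Alternatives chosen before the data were examined were DESeq2 1.42.0 (Wald test, and its size factors in edgeR), no count filter, a block of replicate number, each library left out in turn, doublets kept, nuclei thinned to 1000 UMIs, resolution 2, at most 1% mitochondrial UMIs, at least 2000 UMIs and 1000 genes, shares without TMM, the interaction without the block, and camera with an estimated correlation or fry for lists. Alternatives added after the data were seen were a UMI minimum for each library of 2 times its low-UMI mode (408, 408, 647 and 590 UMIs, with at least 200 genes), and summed counts with free RNA subtracted. The library-specific minimum kept 15201, 16270, 14413 and 11115 nuclei after doublets were removed.

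The fit was tested on simulated data with the means, trended dispersions and library sizes of each class, in 5 simulations of 200 changed genes. Of genes changed 2-fold, 28.2% were recovered in dentate granule, 28.8% in CA1, 30.4% in CA3, 26% in inhibitory and 23% in oligodendrocyte nuclei, and of genes changed 4-fold 82.6%, 81%, 86.4%, 84.4% and 83%. False calls made up 2.94%, 3.45%, 2.63%, 3.13% and 5.48% of the calls. No gene had a spread of its own beyond the trend, and no simulated library was shifted as a whole. The shares recovered and the false calls may therefore be worse in the real libraries. A list of 30 genes raised 1.5-fold had an unadjusted camera p under 0.05 in 5 of 5 simulations in every class. Genes were simulated independently of each other and no unchanged list was tested. This therefore does not show how often camera calls a list of correlated genes wrongly.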

Results

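Single-nucleus RNA sequencing was carried out on the hippocampus of 4 male mice, 2 trained in active place avoidance and 2 untrained. In this task a mouse on a rotating arena learns to keep out of a sector where it receives a mild foot shock. Tissue was taken 3 days after a test of memory retention, with no further recall session, so the comparison asks which transcripts differ in each cell class while the memory is being kept. The mice carried an Arc-driven, tamoxifen-inducible Cre with a floxed eYFP reporter, which marks neurons that expressed Arc around the retention test; nuclei carrying that mark were not analysed here. Each library is taken as 1 mouse, so n = 2 in each group. The p-values of genes, shares and interactions below measure the spread between these 4 samples alone. Those of gene lists by camera with the preset correlation set the genes of a list against the other genes tested. They rest on that assumed correlation and do not measure the spread between mice.

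The deposited UMI counts summed to 23155826 and 26369095 in Trained replicates 1 and 2, and to 39749125 and 24636056 in Untrained replicates 1 and 2. With at least 1000 UMIs and 500 genes per nucleus and probable doublets removed, 739, 4211, 7131 and 6452 nuclei remained, in the same order of libraries. Their median depth was 1143, 1266, 1302 and 1352 UMIs per nucleus before doublets were removed. Trained replicate 1 was therefore the shallowest library, and at this fixed minimum it held the fewest nuclei. With the library-specific minimum it kept 15201, against 14413 and 11115 in Untrained replicates 1 and 2. The fixed minimum thus kept a smaller part of Trained replicate 1 than of the untrained libraries. The median share of mitochondrial UMIs was 0.191% and 0.210% in the trained libraries and 0.362% and 0.315% in the untrained libraries. Xist reached at most 8 UMIs in any library, while Ddx3y, Uty, Kdm5d and Eif2s3y were detected in all 4.

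Clusters were named from marker genes, and the names are rebuilt here. Named classes included CA1 pyramidal-like nuclei (Man1a and 5 other markers higher), CA3 pyramidal-like nuclei (Grik4, Nectin3), dentate granule-like nuclei (Glis3, Maml2, Dock10, Prox1), inhibitory neuron-like nuclei (Erbb4, Nxph1) and oligodendrocyte-like nuclei (Prr5l, St18). The suffix is left out from here on. The other named classes were thalamic excitatory, subicular, astrocyte, ependymal and endothelial nuclei. Glial classes also carried markers of neurons. An oligodendrocyte cluster of 323 nuclei had a mean log2 fold of 0.649 for CA1 markers. The astrocyte clusters had 1.04 for dentate granule, 0.696 for CA1 and 0.636 for cortical markers. Values of glial classes may thus include RNA of neurons. Clusters that reached no name held 31.3% and 28.7% of the nuclei of Trained replicates 1 and 2 and 39.8% and 31.3% of those of Untrained replicates 1 and 2. One of them, led by Itga8, Man1a and Galntl6 and closest to CA1, held 89 and 288 nuclei in the trained and 211 and 163 in the untrained libraries, and is not counted as CA1.

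CA3 pyramidal nuclei made up 18.7% ± 1.83 (SD, n = 2) of the nuclei in trained libraries and 7.06% ± 0.146 (SD, n = 2) in untrained libraries. The 2 trained libraries held 17.5% and 20.04%, and the 2 untrained libraries 7.17% and 6.96%. CA1 pyramidal nuclei stood at 6.22% and 13.5% against 15.8% and 23.6%, a log2 difference of -0.93 (SE 0.48), and dentate granule nuclei at 5.55% and 8.98% against 9.31% and 13.4%, a log2 difference of -0.57 (SE 0.40). Oligodendrocytes made up 8.53% and 6.74% against 5.02% and 5.92%, and thalamic excitatory neurons 17.997% and 6.86% against 7.99% and 5.73%. Of 10 classes tested together, the CA3 share alone passed the threshold, with a log2 difference of 1.47 (SE 0.30, adjusted p = 0.0444 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). An exact two-sided permutation of the 4 libraries gave p = 0.333 for CA3, the smallest that 2 against 2 libraries allow. The adjusted p of the CA3 share in edgeR's quasi-likelihood test rose to 0.241 without Trained replicate 1, 0.190 without Trained replicate 2, 0.439 without Untrained replicate 1 and 0.331 without Untrained replicate 2. With the UMI minimum set for each library, which kept more of the low-depth nuclei, CA3 nuclei made up 13.1% and 10.0% against 4.97% and 5.36% (log2 1.08, SE 0.38, adjusted p = 0.421 by the same test), and the log2 difference was -0.15 (SE 0.32) for CA1 and -0.10 (SE 0.33) for dentate granule nuclei.

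**Figure D1:**
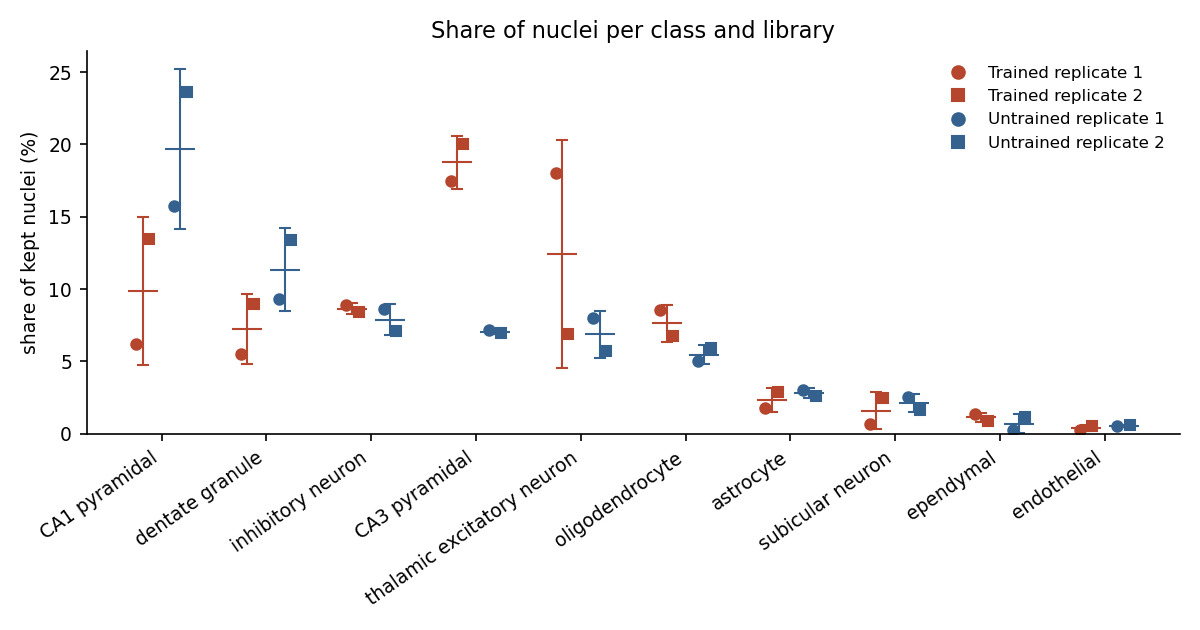
Share of nuclei, in percent of the nuclei kept, for each named class in the 2 trained and 2 untrained libraries; circles are replicate 1, squares replicate 2 and bars the mean ± SD of 2 libraries. The CA3 share was 17.5% and 20.04% in trained libraries and 7.17% and 6.96% in untrained ones.

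In dentate granule nuclei, Ttr (ENSMUSG00000061808), which encodes the thyroid hormone carrier transthyretin and is abundant in choroid plexus, was higher after training, with a log2 change of 1.18 (SE 0.19) and 822 and 911 CPM (counts scaled to the library total after TMM adjustment) in the trained libraries against 335 and 445 in the untrained. Fth1 (ENSMUSG00000024661), the ferritin heavy chain, fell by 0.89 on the log2 scale (SE 0.18), from 2075 and 1962 CPM to 822 and 1214. Cmss1 (ENSMUSG00000022748) fell by 1.08 (SE 0.21) and AY036118 (ENSMUSG00000105361) by 1.06 (SE 0.20). A predicted gene that was singled out after its values were seen, Gm42418 (ENSMUSG00000098178), fell by 0.88 (SE 0.17). Gm42418 and AY036118 are neighbouring transcripts whose reads cannot be told apart from a ribosomal RNA repeat, so their counts are uncertain. Below the threshold, the M-current potassium channel gene Kcnq5 had a log2 change of 1.13 (SE 0.24), the GABA-A receptor subunit gene Gabrg3 0.86 (SE 0.24) and Dennd1b 0.89 (SE 0.24). Among genes of memory and plasticity that were always read out, Homer1 stood at 0.44 (SE 0.24), Arc at -0.44 (SE 0.53), Bdnf at -0.08 (SE 0.32), Prkcz at 0.16 (SE 0.25), Prkci at 0.92 (SE 0.41), Wwc1 at -0.00 (SE 0.28), Camk2a at 0.05 (SE 0.19), Gria1 at 0.05 (SE 0.17) and Grin2b at -0.08 (SE 0.17), none past the threshold.

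Of 9015 genes tested in dentate granule nuclei, 5 passed, 1 higher and 4 lower, with adjusted p from 0.0046 for Ttr to 0.0446 for Fth1 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 5 lay on the same side in both libraries of a group. Barcodes with few UMIs were taken to carry mostly free RNA, which was not tested. In them Ttr had a log2 difference of 1.47 (SE 0.31), Fth1 -0.39 (SE 0.33), Cmss1 -0.72 (SE 0.24), AY036118 -0.71 (SE 0.36) and Gm42418 -0.67 (SE 0.36). Without Untrained replicate 1 edgeR called 0 genes and without Untrained replicate 2 it called 49, while leaving out either trained library gave 8. DESeq2's Wald test called 0 of the genes, and with the UMI minimum set for each library edgeR called Ttr alone.

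In CA1 pyramidal nuclei, 3 genes were higher after training. Ttr had a log2 change of 1.20 (SE 0.21), with 707 and 878 CPM against 307 and 411. Lrrtm4 (ENSMUSG00000052581), a postsynaptic adhesion protein of excitatory synapses, had a change of 1.08 (SE 0.22), with 656 and 332 CPM against 207 and 181. Nr4a3 (ENSMUSG00000028341), an orphan nuclear receptor of the immediate early class, had a change of 1.253 (SE 0.28), with 118 and 91.3 CPM against 44.1 and 35.8. Rnf121 (ENSMUSG00000070426), a RING-type ubiquitin ligase, fell by 1.49 in the fit (SE 0.34), but its libraries overlapped, at 67.3 and 28.9 against 66.8 and 115 CPM, and it was singled out after its values were seen. Below the threshold stood Erbb4 at 1.09 (SE 0.28), the glycolytic enzyme gene Gapdh at -0.95 (SE 0.24), Rnf227 at -1.15 (SE 0.32) and AY036118 at -0.76 (SE 0.21). The scaffold gene Homer1 stood at 0.58 (SE 0.22), with 353 and 432 CPM against 274 and 276, Arc at 0.37 (SE 0.35), Bdnf at 0.15 (SE 0.33), Npas4 at 0.12 (SE 0.51), Prkcz at -0.13 (SE 0.26), Prkci at -0.30 (SE 0.35), Wwc1 at 0.09 (SE 0.25), Camk2a at 0.06 (SE 0.20), Gria1 at -0.10 (SE 0.20) and Grin2b at 0.02 (SE 0.20), none past the threshold.

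Adjusted p values of these CA1 genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 9.61e-05 for Ttr, 0.00987 for Lrrtm4, 0.0255 for Nr4a3 and 0.0255 for Rnf121. Altogether 5 of 10266 genes passed, 3 higher and 2 lower, of which 4 are described here. In Trained replicate 1 the values of Nr4a3 and Rnf121 rest on 7 and 4 UMIs, from 46 nuclei. The low-UMI barcodes gave log2 differences of 0.58 (SE 0.23) for Lrrtm4, 0.40 (SE 0.17) for Nr4a3 and -0.64 (SE 0.16) for Rnf121. Leaving out Untrained replicate 1 or Untrained replicate 2 left edgeR with 0 calls, and leaving out Trained replicate 2 gave 20; without Trained replicate 1 the change of Lrrtm4 was 0.78 (SE 0.21, adjusted p = 0.212 by edgeR's quasi-likelihood test). DESeq2 called 0 of the CA1 genes and, with the UMI minimum set for each library, edgeR called Ttr alone, where Nr4a3 had a log2 change of 0.76 (SE 0.20) and Lrrtm4 1.14 (SE 0.27). Trained replicate 1 and Untrained replicate 1 were also set against the other 2 libraries, a split by replicate number that does not follow training. The same edgeR test called 11 CA1 genes, with 573 at an unadjusted p under 0.05 against 578 for training. At that unadjusted p the split gave 510 against 415 in CA3, 505 against 471 in inhibitory and 528 against 343 in oligodendrocyte nuclei. In dentate granule nuclei it gave 380 against 670. It called 0 genes in those classes. With the library-specific minimum it gave more than training in every class but oligodendrocyte precursors, such as 1212 against 395 in CA1 nuclei.

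**Figure D2:**
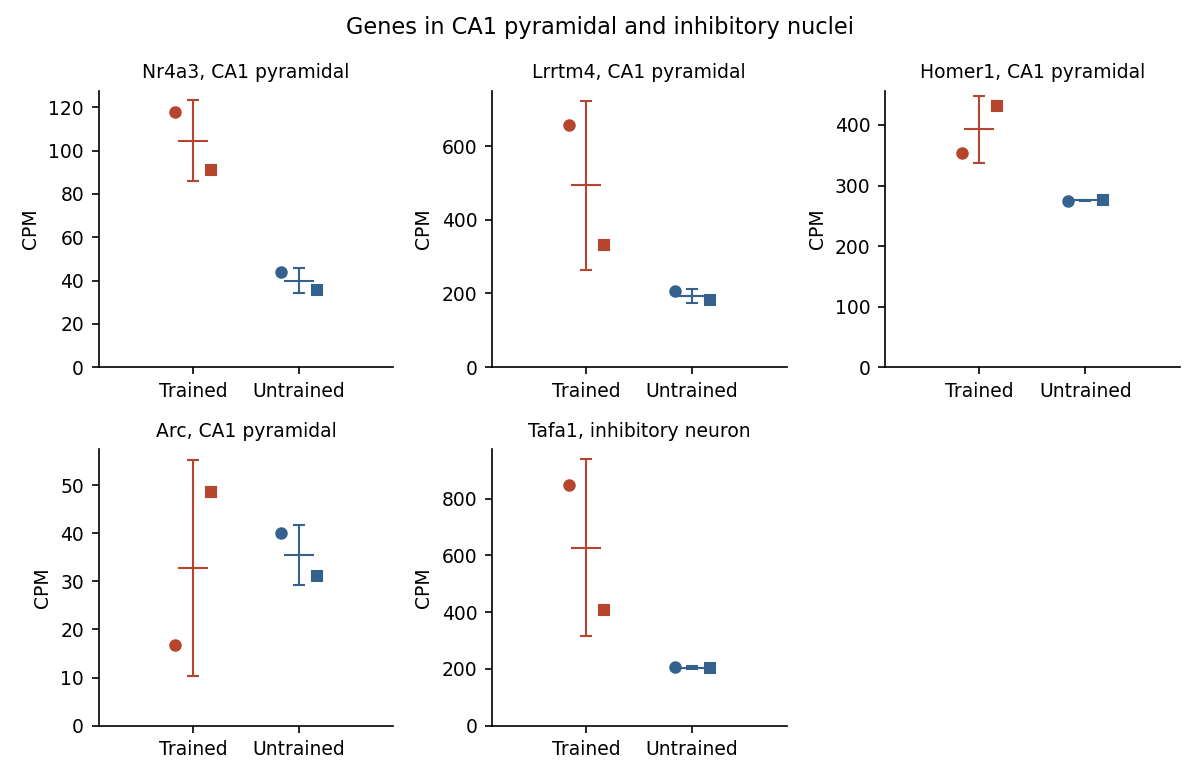
CPM of Nr4a3, Lrrtm4, Homer1 and Arc in CA1 nuclei and of Tafa1 in inhibitory neurons; circles are replicate 1 and squares replicate 2 of each group, and bars give the mean ± SD of 2 libraries. Lrrtm4 in CA1 nuclei stood at 656 and 332 in trained libraries against 207 and 181 in untrained ones.

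In CA3 pyramidal nuclei Ttr was the single gene past the threshold, with a log2 change of 1.65 (SE 0.20) and 588 and 821 CPM in trained libraries against 202 and 260 in untrained ones. Below the threshold, the growth factor gene Nrg1 stood at 0.92 (SE 0.25), Egfem1 at 1.247 (SE 0.35) and the reelin adaptor gene Dab1 at 0.49 (SE 0.14), with 1717 and 1664 CPM for Dab1 against 1272 and 1127. On the lower side, Rnf121 had a log2 difference of -1.45 (SE 0.30), Gapdh -0.89 (SE 0.21), Cmss1 -0.77 (SE 0.19) and C1qtnf4 -0.96 (SE 0.25). The kinase gene Prkci stood at 0.75 (SE 0.31), Wwc1 at 0.40 (SE 0.27), Bdnf at -0.36 (SE 0.37), Homer1 at 0.18 (SE 0.22), Arc at 0.22 (SE 0.47), Prkcz at 0.11 (SE 0.25), Camk2a at 0.09 (SE 0.15), Gria1 at -0.03 (SE 0.13) and Grin2b at 0.10 (SE 0.13), none past the threshold. Ttr had an adjusted p of 0.000756 over 9347 genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and was higher in both trained libraries. Without Untrained replicate 1 the Ttr change was 1.48 (SE 0.26, adjusted p = 0.160 by the same test) and edgeR called 0 genes, while 2 were called without Trained replicate 1 and 27 without Trained replicate 2. With the UMI minimum set for each library, Rnf121 also passed in CA3, with a log2 change of -1.74 (SE 0.24, adjusted p = 0.000933 by edgeR's quasi-likelihood test), but with free RNA subtracted under that minimum edgeR called 0 genes in CA3, with 288 at an unadjusted p under 0.05.

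In inhibitory neurons, Tafa1 (ENSMUSG00000059187), which encodes a secreted chemokine-like protein, was higher after training by a log2 change of 1.45 (SE 0.27), with 847 and 406 CPM against 208 and 202. Ttr was higher by 1.45 (SE 0.23), with 714 and 926 CPM against 263 and 357. Genes below the threshold included Thsd4 at 1.72 (SE 0.38), the semaphorin receptor gene Nrp1 at 1.21 (SE 0.29), Rnf121 at -1.77 (SE 0.37), Mgat4c at -0.89 (SE 0.24), Cnpy2 at -2.52 (SE 0.59) and Lamtor1 at -2.56 (SE 0.69), the last 2 with at most 56.1 CPM in any library. None of the genes always read out passed: Arc stood at 0.58 (SE 0.50), Homer1 at 0.41 (SE 0.26), Prkci at 0.41 (SE 0.36), Wwc1 at 0.39 (SE 0.36), Bdnf at -0.19 (SE 0.52), Prkcz at -0.03 (SE 0.28), Camk2a at 0.15 (SE 0.23), Gria1 at 0.20 (SE 0.21) and Grin2b at 0.16 (SE 0.21). Over 8512 genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave an adjusted p of 0.00924 for Ttr and 0.0486 for Tafa1. The low-UMI barcodes gave 0.56 (SE 0.16) for Tafa1. The change of Tafa1 was 0.99 (SE 0.26) without Trained replicate 1, where it no longer passed edgeR's quasi-likelihood test, and the number of called genes was 9 without that library, 8 without Trained replicate 2 and 1 without Untrained replicate 1, a lower gene, where neither Ttr nor Tafa1 passed. With probable doublets kept, Tafa1 stood at 0.97 (SE 0.22, adjusted p = 0.505 by edgeR's quasi-likelihood test).

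**Figure D3:**
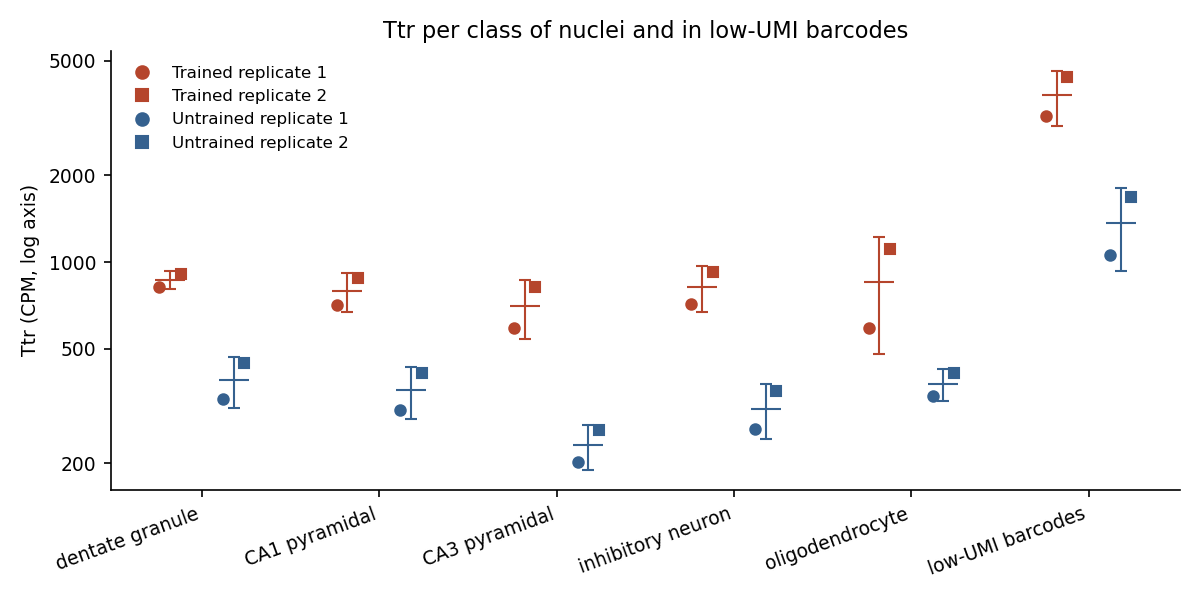
CPM of Ttr (log axis) in each class tested and in the low-UMI barcodes; circles are replicate 1, squares replicate 2 and bars the mean ± SD of 2 libraries. In CA3 nuclei the trained libraries stood at 588 and 821 and the untrained ones at 202 and 260.

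In oligodendrocytes Ttr stood at 1.24 (SE 0.26), with 590 and 1113 CPM against 344 and 413, Thsd4 at 1.48 (SE 0.37), the T-type calcium channel gene Cacna1h at 1.45 (SE 0.42) and the haemoglobin gene Hbb-bs at 1.12 (SE 0.33), none past the threshold. Lower values that did not pass were those of Cmss1 at -1.06 (SE 0.26), Cdyl at -2.18 (SE 0.59), Upf3a at -2.93 (SE 0.82) and Wbp4 at -1.56 (SE 0.45). Homer1 stood at 0.77 (SE 0.28), Arc at 0.19 (SE 0.45), Bdnf at -0.15 (SE 0.50), Prkcz at -0.15 (SE 0.31), Prkci at 0.25 (SE 0.46), Wwc1 at -0.19 (SE 0.35), Camk2a at 0.03 (SE 0.24), Gria1 at 0.21 (SE 0.23) and Grin2b at 0.29 (SE 0.22). Part of these nuclei also carried CA1 markers, so such values cannot be placed in oligodendrocytes alone. In this class edgeR's quasi-likelihood test called 0 of 7678 genes, with 343 at an unadjusted p under 0.05, and DESeq2 called 0; the adjusted p of Ttr was 0.174 with Benjamini-Hochberg adjustment. Without Untrained replicate 2 edgeR called 7 genes, and without Trained replicate 1 it called 1.

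Astrocytes could not be tested at 1000 UMIs with all 4 libraries, because Trained replicate 1 held 13 of them; without that library edgeR called 0 of 6010 genes, with 259 at an unadjusted p under 0.05. DESeq2 was not run on those 3 libraries. With the UMI minimum set for each library, Rnf121 fell by 2.97 (SE 0.39) in astrocytes, to 18.3 and 32.7 CPM from 135 and 301 (adjusted p = 0.00122 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Rnf121 was the single gene called of 8959, and 0 genes were called with free RNA subtracted (158 at an unadjusted p under 0.05). The make-up of this class differed by library. An astrocyte cluster with a mean log2 fold of 0.359 for dentate granule markers held 508 and 325 nuclei in the trained and 315 and 192 in the untrained libraries. Another, with 1.116 for oligodendrocyte markers, held 103 and 765 against 344 and 352. Oligodendrocyte precursors reached 30 nuclei in every library with that lower minimum alone, where edgeR called 0 of 3158 genes, with 153 at an unadjusted p under 0.05, and DESeq2 called 1. No cluster was named microglia, and that class was not analysed here.

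Transcripts of cytosolic ribosomal proteins were lower after training as a group in all 5 classes tested. Their median log2 change was -0.59 in dentate granule, -0.48 in CA1, -0.37 in CA3, -0.48 in inhibitory and -0.53 in oligodendrocyte nuclei. In dentate granule nuclei, 64 of 80 ribosomal protein genes lay lower in both trained libraries than in both untrained ones. Of these 80, 37 fell when p was adjusted over the list alone and 0 over all genes tested; Rplp1 stood at -0.90 (SE 0.21) and Rpl28 at -1.01 (SE 0.26). In CA1 nuclei 13 of 80 fell with p adjusted over the list alone, and 0 did in the other 3 classes. The list passed in all 5 classes, with adjusted p from 1.03e-16 to 1.39e-08 by limma's camera with a preset correlation and Benjamini-Hochberg adjustment. It passed in none when the correlation was estimated (adjusted p = 0.571 to 0.808 with an estimated correlation). With free RNA subtracted, the list of cytosolic ribosomal proteins passed in oligodendrocytes alone, and its median was 0.03 in CA1 and 0.32 in CA3 nuclei.

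Genes encoded by the mitochondrial genome were lower after training in the same 5 classes, with median log2 changes from -0.90 in oligodendrocytes to -0.50 in CA3 nuclei. Adjusted over the list alone, 9 of 13 fell in dentate granule nuclei, 10 of 13 in CA1, 7 of 13 in CA3, 7 of 11 in inhibitory neurons and 9 of 11 in oligodendrocytes, and 0 did over all genes tested. In dentate granule nuclei mt-Atp6 stood at -0.79 (SE 0.20), mt-Cytb at -0.86 (SE 0.24) and mt-Co1 at -0.67 (SE 0.19). Nuclear genes of oxidative phosphorylation had medians from -0.45 in dentate granule to -0.29 in CA3 nuclei; adjusted over the list alone, 8 of 31 fell in dentate granule nuclei, 1 of 31 in CA1 and 0 in the other 3 classes. Cox6a1 stood at -1.24 (SE 0.29) and Cox6c at -0.98 (SE 0.24) in dentate granule nuclei. With limma's camera, adjusted p ran from 2.01e-08 to 0.000301 for the mitochondrially encoded list and from 9.98e-05 to 0.00283 for the nuclear one; neither passed with the correlation estimated (adjusted p = 0.571 to 0.808 with an estimated correlation). With free RNA subtracted, the mitochondrially encoded list passed in all 5 classes and the nuclear one in none. The low-UMI barcodes moved the same way, with medians of -0.32 for ribosomal proteins, -0.37 for mitochondrially encoded genes and -0.31 for oxidative phosphorylation.

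Chaperone genes were lower as a group in dentate granule nuclei (median -0.57; Hspe1 -1.17, SE 0.36, libraries overlapping; Hspa8 -0.57, SE 0.19; Hsp90ab1 -0.53, SE 0.19), where 3 of 13 fell with p adjusted over the list alone. Kainate and metabotropic glutamate receptor genes were higher as a group in CA1 nuclei (median 0.15; Neto2 0.54, SE 0.27; Neto1 0.43, SE 0.26; Grm7 0.33, SE 0.20), and synaptic adhesion genes in CA3 nuclei (median 0.15; Lrrtm4 0.56, SE 0.21; Ptprd 0.45, SE 0.17; Tenm1 0.75, SE 0.29), with 0 members of either past the threshold adjusted over the list alone. Choroid plexus transcripts were higher in CA3 nuclei (median 0.82), where 2 of 5 rose with p adjusted over the list alone, among them Ttr, and Enpp2 stood at 0.82 (SE 0.25). Unfolded protein response genes were lower in oligodendrocytes (median -0.37; Hspa5 -0.80, SE 0.35; Atf4 -1.38, SE 0.63), with 0 of 11 past the threshold over the list alone. Camera's adjusted p values for these 5 were 0.0148, 0.00577, 0.0191, 0.00228 and 0.00267, in the order given, against adjusted p = 0.571, 0.808, 0.636, 0.636 and 0.763 with an estimated correlation. In the low-UMI barcodes the same 5 lists had medians of -0.23, 0.31, 0.13, 0.90 and -0.20.

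No immediate early gene list passed at 1000 UMIs: its adjusted p ran from 0.326 to 0.777 by camera, with class medians from -0.32 to 0.29, and Nr4a3 in CA1 was the one member called over all genes. In CA1 2 of 14 members rose with p adjusted over the list alone, Nr4a3 and Homer1, while Egr3 stood at -1.31 (SE 0.52). Camera gave the direction as up in dentate granule and CA3 nuclei, where the medians were -0.32 and -0.01 and the means -0.12 and -0.03. Of 29 lists tested, 21 passed in no class; the lowest adjusted p among them was 0.0736, for translation factors. Late activity-response genes ranged from 0.125 to 0.706, glycolysis genes from 0.0919 to 0.194, voltage-gated sodium and calcium channels from 0.0864 to 0.709 and chromatin regulators from 0.101 to 0.695. The AMPA receptor list ranged from 0.163 to 0.706, the memory kinase list from 0.252 to 0.777 and the postsynaptic scaffold list from 0.0919 to 0.541. Of 134 tests of a list in a class, 20 passed with the preset correlation. With the correlation estimated for each list none passed, and the lowest was adjusted p = 0.571 by camera with an estimated correlation. With 4 libraries in 2 groups, few residual degrees of freedom are left for that estimate. The test then has little power, so it neither refutes nor bears out the 20 calls. The number of calls fell to 7 without Trained replicate 2.

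**Figure D4:**
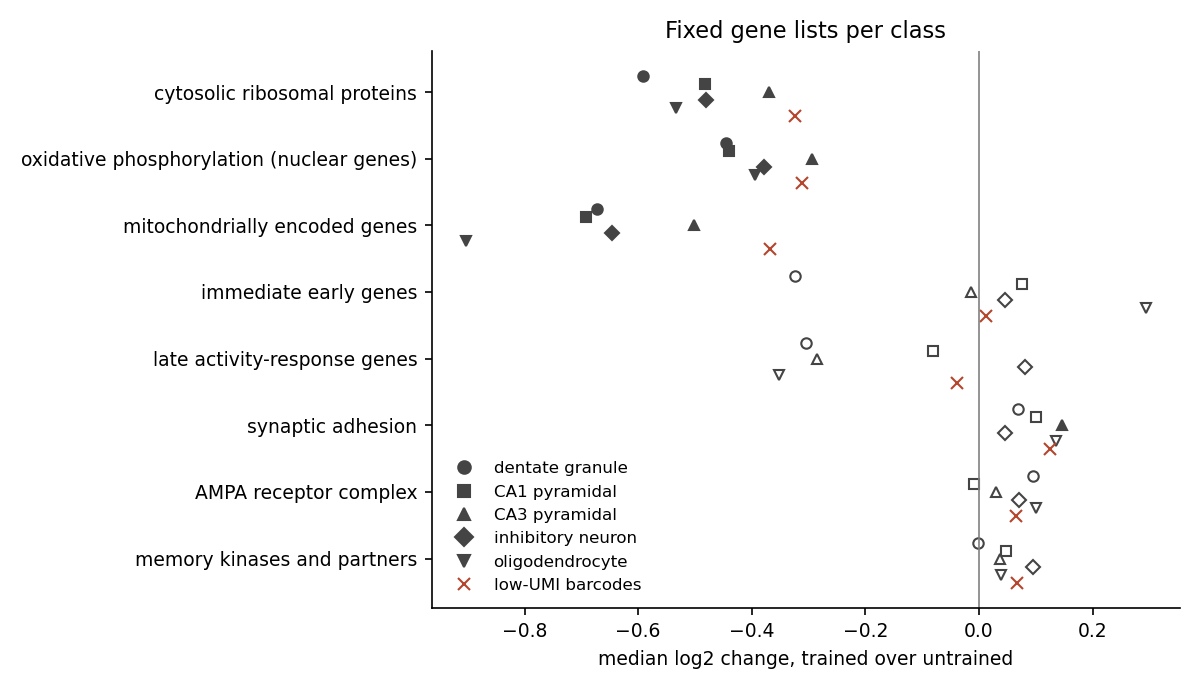
Median log2 change, trained over untrained, of 8 of the fixed gene lists; each shape is 1 cell class, filled where camera's adjusted p was under 0.05, and crosses are the low-UMI barcodes. Ribosomal protein medians lie between -0.59 and -0.37 in the 5 classes, with the low-UMI barcodes at -0.32.

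Whether the effect of training differed between the principal neuron classes was tested as an interaction for each pair of dentate granule, CA1 and CA3 nuclei. St6galnac3 (ENSMUSG00000052544), a sialyltransferase gene, had a log2 change of 0.58 (SE 0.21) in dentate granule and -0.41 (SE 0.24) in CA1 nuclei, and the interaction fit gave a difference of 1.09 (SE 0.21, adjusted p = 0.00386 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It was 1 of 10494 genes in that pair, with 376 at an unadjusted p under 0.05. The difference for Lrrtm4 between dentate granule and CA1 nuclei was -0.80 (SE 0.19) and did not pass (adjusted p = 0.152 by the same edgeR test). For dentate granule against CA3 and for CA1 against CA3, edgeR called 0 of 10498 and 0 of 10333 genes, with 386 and 365 at an unadjusted p under 0.05; DESeq2 was not run for the interaction. For dentate granule against CA1 the count was 0 without Trained replicate 1, without Untrained replicate 1 or without Untrained replicate 2, and 8 without Trained replicate 2; it was also 0 without the library block and with the library-specific UMI minimum. In the other pairs, leaving out Trained replicate 1 gave 1 and 2 calls and leaving out Trained replicate 2 gave 21 and 33.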

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

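The tests of free RNA for single genes and for Ttr below were chosen only after the result was seen; the tests of all called genes and of the splits were written before.

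In the low-UMI barcodes, which the comparisons of nuclei do not use, Ttr had a log2 difference of 1.47 (SE 0.31, adjusted p = 0.467 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with 3217 and 4374 CPM in trained against 1059 and 1677 in untrained libraries. It stands here because it is a signal in data outside the nuclei.

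The genes called in the classes, Ttr among them, were weighed against free RNA that differs between the libraries. The low-UMI barcodes stood for that RNA, and every estimate below rests on this. They held nuclear RNA too: RNA in their amount would bring 3.91% to 10.5% of the UMIs of the nuclear transcript Malat1 in the classes. For Ttr, free RNA in the amount of the low-UMI barcodes would bring a median of 83.5% of its UMIs in nuclei (65.9% to 113% over 20 class and library values). That goes with RNA from choroid plexus. With free RNA subtracted, Ttr still passed in inhibitory neurons alone, and in no class with the library-specific UMI minimum. Nuclei named choroid plexus under that minimum made up 0.724% and 0.695% of the trained libraries against 0.0902% and 0.414% of the untrained ones. The trained libraries thus also held a larger share of choroid plexus nuclei. Whether that came with the dissection or with training stays open and was not tested. For Nr4a3 and Rnf121 in CA1 and Tafa1 in inhibitory neurons the median was 14.5% (7.22% to 33.8% over the single libraries). Free RNA in this amount thus brings the smaller part of their UMIs in every library. However, with free RNA subtracted none of these 3 passed (Nr4a3 at 1.31, SE 0.35). For the other called genes, among them Lrrtm4 (37.3%), Fth1, Gm42418, AY036118 and Cmss1, the median was 72.6%. For these, free RNA cannot be told apart from a change in the nuclei, since its amount per nucleus is itself estimated. After subtraction 2 genes were called in dentate granule nuclei, both lower, and 0 in CA1. Among all 13 pairs of a called gene and a class, 3 (23.1%, exact 95% interval 5.04% to 53.8%) had at least the same change in the low-UMI barcodes, all 3 of them Ttr, which makes up 4 of the pairs with a single low-UMI value, while in the 9 other pairs the change there was at most 0.762 of that in the class; the interval counts repeats of 1 gene as independent and is too wide to settle the explanation. Of the 3 ways to split 4 libraries into pairs, 1 gave at least the 13 calls of the real split, namely the real one, and the highest other, Trained replicate 1 with Untrained replicate 1, gave 11, all in CA1, where the real split gave 5; 3 splits are too few for a share under 0.05.

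St6galnac3 stands out because its training effect differs between classes: the interaction of dentate granule minus CA1 nuclei was 1.09 (SE 0.21, adjusted p = 0.00386 by edgeR's quasi-likelihood test), with 0.58 in dentate granule and -0.41 in CA1 nuclei.

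With the library-specific UMI minimum, 5 genes stand out because their training effects differ between CA1 and CA3 nuclei, by the interaction in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Lrrtm4 had a difference of 1.01 (SE 0.16, adjusted p = 0.0091; 1.14 in CA1 and 0.06 in CA3), the ephrin receptor gene Ephb1 1.63 (SE 0.29, adjusted p = 0.022; 1.245 and -0.40) and the glypican gene Gpc5, which is among the leading genes of the astrocyte clusters and whose class's markers had a median of 0.31 in the low-UMI barcodes, -0.83 (SE 0.15, adjusted p = 0.022; -0.13 and 0.70). Trps1, which leads the CA3 cluster, had 0.77 (SE 0.15, adjusted p = 0.0317; 0.36 and -0.42) and Mgat4c 0.64 (SE 0.13, adjusted p = 0.0415; 0.38 and -0.25). Without Trained replicate 1 edgeR called 0 genes for this pair of classes and without Trained replicate 2 it called 46. It also called 0 without the library block and 0 with free RNA subtracted, and without Untrained replicate 1 it called 15. The nuclei compared are unlike in depth, with a median of 501, 785, 1012 and 1142 UMIs in CA1 and 582, 1110, 1360 and 1624 in CA3 nuclei (Trained replicates 1 and 2, Untrained replicates 1 and 2). At resolution 2 they also lie in different clusters: a CA3 cluster with a median of 613 UMIs held 1527, 463, 130 and 77 nuclei, and an unnamed cluster nearest to CA1 with a median of 595 UMIs held 1972, 1047, 571 and 483.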

How the results depend on the processing

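With 2 libraries in a group, and 41 to 129 nuclei of each principal class in Trained replicate 1, single libraries decide most calls. Of 124 counts under an alternative, 50 stayed within 1.5 times and 74 moved; of the values for named genes and the CA3 share, 1094 kept their side of the threshold, 38 became called and 72 were no longer called. The called genes inside the naming rule kept their direction in every alternative, 11 of 11, or 10 of 10 with free RNA subtracted. The rule takes only genes whose trained libraries lie on 1 side of both untrained ones, so a kept direction says little. With all 4 libraries, 2 of 11 (DESeq2's Wald test) to 11 of 11 (DESeq2 size factors, resolution 2) were still called. With free RNA subtracted, 2 of 10 were still called. The CA3 share also kept its direction. Except where fewer libraries or fewer UMIs are used by construction, the cause was not tested. Tests of genes, lists and interactions with at least 2000 UMIs were not run because too few nuclei were left, and microglia and the eYFP comparisons were not run. With one library left out, the lone sample of its group is assumed to vary like the other group.

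Genes called by edgeR were 5 in dentate granule, 5 in CA1, 1 in CA3, 2 in inhibitory and 0 in oligodendrocyte nuclei, and with the library-specific minimum 1 in astrocytes and 0 in oligodendrocyte precursors. Leaving out 1 library at a time gave 0 to 49 in dentate granule, 0 to 20 in CA1, 0 to 27 in CA3, 1 to 9 in inhibitory, 0 to 7 in oligodendrocyte, 0 to 28 in astrocyte and 0 to 19 in oligodendrocyte precursor nuclei. DESeq2's Wald test gave 0 in dentate granule, 0 in CA1, 1 in inhibitory, 2 in astrocyte and 1 in oligodendrocyte precursor nuclei. Without a count filter there were 2 in dentate granule, 1 in CA1, 5 in CA3, 6 in inhibitory, 2 in astrocyte and 2 in oligodendrocyte precursor nuclei. With doublets kept there was 1 in inhibitory, 2 in astrocyte and 1 in oligodendrocyte precursor nuclei; at resolution 2, 17 in dentate granule nuclei; with at most 1% mitochondrial UMIs, 1 in CA1 and 1 in oligodendrocyte nuclei; thinned to 1000 UMIs, 2 in CA1 and 10 in inhibitory nuclei. With free RNA subtracted there were 2 in dentate granule, 0 in CA1, 0 in CA3 and 1 in inhibitory nuclei, and with the library-specific minimum 0 in all 7 classes, astrocytes among them. The library-specific minimum gave 1 in dentate granule, 1 in CA1, 2 in CA3, 1 in inhibitory and 2 in oligodendrocyte nuclei.

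The 20 list calls became 0 with an estimated correlation, 1 with fry directional, 0 with fry mixed, 7 to 20 with 1 library left out, 7 with free RNA subtracted and 31 with the library-specific minimum. The 1 share called, that of CA3, became 0 without TMM, at resolution 2, with the library-specific minimum and with any library left out (0 to 0); with at least 2000 UMIs the CA3 share had a log2 difference of 0.11 (SE 0.42), with 1 CA3 nucleus in Trained replicate 1, and the 1 class called was inhibitory neurons, at -2.68 against 0.19, while the thalamic share stood at -1.28 (SE 0.49) against 0.90, neither called with the fixed minimum of 1000 UMIs. The inhibitory call at 2000 UMIs rests on 0 and 2 nuclei in Trained replicates 1 and 2, against 27 and 42 in the untrained libraries. The thalamic share there rests on 1 and 16 against 74 and 150 nuclei. With free RNA subtracted, the median of the ribosomal list went from -0.48 to 0.03 in CA1 and from -0.37 to 0.32 in CA3 nuclei. That of oxidative phosphorylation went from -0.29 to 0.03 in CA3 nuclei. The 1 interaction became 2 without a count filter, 0 without the library block, 0 to 62 with 1 library left out, 6 with free RNA subtracted and 5 with the library-specific minimum.

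The replicate numbers name the samples and give 2 pairs, so pairing is only a possibility. The correlation within a replicate number was -0.0117 to 0.0284 over the 5 classes with the fixed minimum and 0.0331 to 0.121 over the 7 classes with the library-specific minimum. However, under the latter, a split by replicate number gave 1212 genes at an unadjusted p under 0.05 in edgeR's quasi-likelihood test in CA1 nuclei, against 395 for training. In CA3 nuclei it gave 1172 against 294. Only in oligodendrocyte precursors did it not exceed training. The main fit leaves out this difference between replicate numbers, and its cause was not tested. With the replicate number as a block there were 12 calls in dentate granule, 4 in inhibitory, 2 in oligodendrocyte and 2 in astrocyte nuclei, and 0 shares. With the library-specific minimum the block gave 4 calls against 1 in dentate granule, 10 against 1 in CA1 and 2 against 1 in inhibitory nuclei. The counts in CA1 and CA3 nuclei with the fixed minimum stayed at 5 and 1, and 19 lists were called against 20.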

Other observations

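With the fixed UMI minimum, the list of cholesterol synthesis genes passed in 0 of 5 classes. Its class medians there ran from -0.30 to 0.08, with adjusted p from 0.695 to 0.897 by camera with the preset correlation. With the UMI minimum set for each library, genes of cholesterol synthesis were higher after training as a group in dentate granule nuclei (18 of 19 positive, median log2 change 0.21), CA1 nuclei (17 of 19, median 0.24) and inhibitory neurons (9 of 13, median 0.28). The desaturase gene Sc5d stood at 0.48 (SE 0.24) in dentate granule nuclei, Msmo1 at 0.42 (SE 0.23) in CA1 nuclei, and Cyp51 at 0.73 (SE 0.33) and Msmo1 at 0.62 (SE 0.30) in inhibitory neurons, none called alone, while Fdps stood at -0.43 (SE 0.21) in dentate granule nuclei. Camera's adjusted p was 0.00159, 0.00297 and 0.0273 in these 3 classes, against adjusted p = 0.812, 0.582 and 0.932 with an estimated correlation, and 0 members passed with p adjusted over the list alone. Without Trained replicate 1 the adjusted p of the cholesterol synthesis list was 0.184 in dentate granule and 0.263 in CA1 nuclei, and without Untrained replicate 2 it was 0.185 in CA1 nuclei.

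Immediate early genes were higher as a group under the same minimum in dentate granule (12 of 16 positive, median 0.17) and CA1 nuclei (12 of 17, median 0.28). Nr4a3 stood at 0.76 (SE 0.20), Arc at 0.63 (SE 0.20) and Homer1 at 0.38 (SE 0.17) in CA1 nuclei, and the phosphatase gene Dusp1 at 1.13 (SE 0.35) and Nr4a1 at 0.87 (SE 0.32) in dentate granule nuclei; 1 of 17 rose in CA1 with p adjusted over the list alone. Camera's adjusted p was 0.00596 and 0.0386, against adjusted p = 0.843 and 0.582 with an estimated correlation. Without Trained replicate 1 the immediate early gene list had adjusted p = 0.383 in dentate granule and 0.578 in CA1 nuclei, and without Untrained replicate 1 it had 0.943 and 0.159. Myelin genes were also higher in dentate granule (median 0.28), CA1 (0.36), CA3 (0.34) and inhibitory nuclei (0.31; camera's adjusted p = 0.000197, 0.000359, 0.000822 and 0.0172, against adjusted p = 0.582 or more with an estimated correlation). They were not called in oligodendrocytes (0.06) and had a median of 0.22 in the low-UMI barcodes.

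For the patterns below, the tests of the 3 lists were chosen only after the result was seen; both tests of the CA3 share were written before.

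Lower ribosomal, oxidative phosphorylation and mitochondrially encoded transcripts in trained nuclei were weighed against less free cytoplasmic RNA in the trained libraries. In the low-UMI barcodes the ribosomal list had a median of -0.32 (first quartile -0.38; -0.59 to -0.37 in the classes), and after free RNA was subtracted the class medians ran from -0.41 to 0.32. For oxidative phosphorylation the median was -0.31 (first quartile -0.39; -0.45 to -0.29 in the classes), and -0.22 to 0.03 after subtraction, so for these 2 lists free RNA and a change in the nuclei cannot be told apart, since the amount to subtract is estimated. For mitochondrially encoded genes the median was -0.37 (first quartile -0.44), against -0.90 to -0.50 in the classes and -1.41 to -0.79 after subtraction. The fall in the low-UMI barcodes was smaller than in any class, the outcome set as counting against free RNA of this composition. The amount of free RNA also differed, with modes of 204 and 204 UMIs in trained against 324 and 295 in untrained libraries. Since that amount is estimated, free RNA is not excluded as the whole cause. An effect of training on these transcripts, or cytoplasm left on the nuclei, stays open and was not tested.

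The larger share of CA3 nuclei was weighed against more CA3 tissue in the trained samples and against the fixed UMI minimum. CA3 marker genes had a median log2 difference of 0.51 in the low-UMI barcodes (7 of 7 positive, 0.04 to 1.06), against 0.04 for CA1 and 0.25 for dentate granule markers, which is consistent with more CA3 tissue. The value lies just above the bound of 0.5 set for it, and the markers of 3 classes outside the pyramidal layer were higher, at 0.94 for fibroblasts, 0.87 for choroid plexus and 0.57 for mural cells. The make-up of nuclei also differed within the untrained group. An unnamed cluster nearest to cortical markers held 393 and 68 nuclei in Untrained replicates 1 and 2, against 3 and 8 in the trained libraries. At the fixed minimum, an unnamed cluster nearest to CA2 and then CA3 markers was not counted as CA3. It held 36 and 216 nuclei in the trained and 99 and 108 in the untrained libraries. Its leading genes Col11a1, Cpne4 and Kcnq5 also lead the CA3 cluster of the library-specific minimum, so the CA3 classes compared may differ. At the fixed minimum the log2 difference of the CA3 share was 1.47 (SE 0.30, adjusted p = 0.0444 by edgeR's quasi-likelihood test). With the library-specific minimum it was 1.08 (SE 0.38, adjusted p = 0.421 by the same test). The call was thus lost, the outcome set beforehand for the fixed minimum as the cause. The log2 difference stayed positive, and its drop is similar in size to the errors of the estimates, which share libraries and nuclei. Loss of the call alone therefore cannot settle the part of the fixed minimum. A gain of CA3 nuclei through training was not tested.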
